A study of Mus musculus with 22 samples.

How the data were processed

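Astrocyte RNA from mouse visual cortex was obtained by pulling down ribosomes tagged on Rpl22 in cells with a GFAP-cre driver, and 1 input per group was sequenced beside the pulldowns. Per the labels, 22 samples made up the series, 17 pulldowns and 5 inputs. Of these, 21 libraries were used, 16 pulldowns and 5 inputs, because dark-reared replicate 2 was not analysed here. In addition, 1 column of another sample in the table was not used. Pulldown libraries numbered 3 for normal rearing at postnatal day 45, 4 for dark rearing at day 45, 3 for 10 days of darkness at day 120, and 3 each for the contralateral and ipsilateral cortex after 2 days of monocular deprivation at day 28.

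The deposited values were FPKM per gene and library as the authors made them, for 24537 genes with 1 RefSeq transcript each, rounded to 0.1. Per the submitters' processing notes, the tools were CASAVA 1.8.2, FastQC 0.11.2, STAR 2.5.1b, HOMER 4.10, R 3.4.3 and DESeq2, on mm10, without their order. The authors' group averages, also FPKM, were checked against the library columns and differed by at most 0.075 FPKM. Gene names that a spreadsheet had turned into dates were restored for 26 genes. Counts were not among the values used. Depth was therefore estimated from the steps between values of genes shorter than 130 bases, where 1 read makes a visible step. It came to 21.3 to 51.5 M reads over 20 libraries, and contralateral replicate 2 had no clear steps. Rounding to 0.1 FPKM limits the precision of genes near 1 FPKM, and counting error could not be separated from it.

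Values were analysed as log2(FPKM + 1). Genes with a mean above 1 FPKM over the libraries of a fit were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust settings), 2-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. All 16 pulldown libraries shared 1 estimate of the spread, where the plan had counted 17. The monocular libraries varied more than the others. Libraries within a monocular group correlated at 0.962 to 0.982, and dark-reared libraries at 0.992 to 0.998. The spread of the monocular libraries enters the error of every comparison between pulldown groups, so a low count does not show that genes stayed unchanged. Pulldown and input were compared over all 21 libraries with a term for the group. The difference between the effects of dark rearing and of monocular deprivation was tested as a contrast in the same fit, and the fold changes of both were correlated across genes.

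Before the data were examined, 32 gene lists were fixed, with 426 genes written out and the rest given by name patterns, and 30 had enough measured members to test. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Named genes followed a fixed rule. The 10 largest increases and 10 largest decreases past the threshold with groups that did not overlap were named, and the 10 smallest p values where fewer than 20 genes passed. From each list, up to 4 passing genes or else 2 with the smallest p were added, and 7 fixed genes (Gfap, Gja1, Gjb6, Aldh1l1, Chrdl1, Gpc4 and Rpl22) could be named in every comparison. Pseudogenes, predicted genes without a symbol of their own and sex-linked genes were not named among the largest changes. Arc in the comparison of dark with normal rearing, and Etnppl in the blocked difference, fell outside the rule and were chosen after their values were seen. Gene positions came from GENCODE vM21 on GRCm38, the same assembly as mm10.

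Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 5 FPKM, quantile normalization, median-ratio scaling, array weights, genes at or above 0.75 of input, only the groups compared, 5 inputs against 5 group means, no term for the group, a covariate for other cell types (the mean over 6 marker lists, microglia among them), the replicate number as a block, and leaving out each library in turn. Added after seeing the data were covariates for neuron markers and for Rn45s, scaling without Rn45s and Mir6236, the monocular pairs as a block in the difference of the effects, fits without the monocular pair 2, and fits without the 3 pulldown libraries with Rn45s below 1000 FPKM. The fits were tested on simulated data with known changes. A change of 1 on the log2 scale was recovered for 50.0% to 65.2% of changed genes in the comparisons between pulldown groups and for 95.3% in pulldown against input. A change of 0.5 was recovered for 7.46% to 19.7% between pulldown groups, and false calls ran from 2 of 97 calls to 10 of 118. The simulated noise was independent between genes and libraries, without the likeness of numbered pairs, so recovery in the real data is not known. Python 3.11.15 with pandas 2.3.3 prepared the tables and matplotlib 3.10.9 drew the figures.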

Results

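The series profiled RNA bound to tagged ribosomes of astrocytes in the mouse visual cortex after manipulations of visual experience. A GFAP-cre driver placed a hemagglutinin tag on the ribosomal protein Rpl22, and ribosomes were pulled down through the tag before poly(A) RNA sequencing. The 5 groups compared each came with an input library, which is RNA of the same tissue before the pulldown. The groups were normal rearing to postnatal day 45 (3 pulldown libraries), dark rearing from birth to day 45 (4 libraries), 10 days of darkness ending at day 120 (3 libraries), and the cortex contralateral (3 libraries) and ipsilateral (3 libraries) to an eye closed for 2 days at day 28. In all, 16 pulldown and 5 input libraries were used, with values in FPKM, which scales fragments to transcript length and library size. Estimated depth ran from 21.3 to 51.5 M reads over 20 of the libraries, and no estimate could be had for contralateral replicate 2, which had the fewest genes above 0, 14092. Errors after a mean are SD over libraries and errors after a log2 fold change are SE from limma. Coordinates are on GRCm38 (mm10), counted from 1.

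The first comparison asked which transcripts the pulldown enriched over whole cortex. Astrocyte transcripts stood far above the input, and transcripts of neurons and microglia far below it. Aldoc, a glycolytic aldolase of astrocytes (chromosome 11, 78322968 to 78327781), rose by 3.52 ± 0.10 on the log2 scale, from a mean of 407.5 FPKM in 5 inputs to 4649 FPKM in 16 pulldowns. Sst, the neuropeptide somatostatin of cortical interneurons (chromosome 16, 23889573 to 23890958), had a log2 fold change of -5.49 ± 0.20, with 5.83 FPKM in the pulldowns and 306.1 FPKM in the inputs. Of 12070 genes tested, 9300 passed, 3185 higher and 6115 lower in the pulldown. The median log2 fold change over all genes was -0.31, and it was 0.01 after quantile normalization, with 4646 genes higher and 4638 lower, and 0.02 after median-ratio scaling, with 4552 higher and 4527 lower.

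All 22 measured astrocyte markers rose (22 when adjusted over the list alone), with a median log2 fold change of 2.68. Among them were Acsbg1, an acyl-CoA synthetase, at 3.41, Aldh1l1, a folate enzyme used as an astrocyte marker, at 3.18, and Glul, glutamine synthetase, at 3.19. The largest increases took in Apoe, the lipid carrier, at 3.68, Tst, a sulfurtransferase, at 3.56, Mfge8, a secreted bridge for phagocytosis, at 3.48, Cbs, an enzyme of cysteine synthesis, at 3.39, Htra1, a secreted protease, at 3.38, Gstm1, a glutathione transferase, at 3.37, and Prodh, proline dehydrogenase, at 3.37. Gfap, the intermediate filament of astrocytes, rose by 3.36, and the connexins Gjb6 and Gja1 by 2.60 and 2.68. Of 14 measured genes for transmitter uptake and potassium buffering, 13 rose, including the glutamine carrier Slc38a3 at 3.01 and the GABA carrier Slc6a11 at 2.79. In the cholesterol synthesis list 19 of 21 genes rose, with Mvd at 2.57 and Msmo1 at 2.26. All 13 measured genes of Notch and Hedgehog signalling rose, including Hes5 at 2.19 and Smo at 1.76.

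All 19 measured neuron markers had lower levels in the pulldown, with a median log2 fold change of -2.46, and all 14 microglia markers did, with a median of -3.11. Gad1, which makes GABA, was at -3.95, Slc32a1, the vesicular GABA carrier, at -3.68, Vip at -4.38 and Pvalb at -4.29. Among microglial genes, Ctss, a lysosomal protease, was at -3.89 and Cx3cr1, the fractalkine receptor, at -3.32. The 20 measured immediate early genes, which respond within minutes to cell activity, were all lower, with a median of -1.88 and with Homer1 at -2.44 and Nr4a2 at -2.45. Of 12 oligodendrocyte markers 7 rose and 0 fell, with Cnp at 1.70 and Mag at 1.37, and of 10 precursor markers 8 rose, with Olig1 at 1.48, and 1 fell, Lhfpl3 at -0.66. By camera with a preset correlation, the adjusted p was 1.77e-15 for the astrocyte, 1.91e-05 for the neuron and 1.91e-05 for the microglia list. With an estimated correlation these became adjusted p = 0.187 for astrocytes, adjusted p = 0.382 for neurons and adjusted p = 0.382 for microglia, and 0 of 30 lists passed, against 19 with the preset correlation. By fry the adjusted p was 3.48e-13 for the astrocyte, 4.94e-10 for the neuron and 6.09e-10 for the microglia list. Camera with an estimated correlation thus did not pass a list whose 22 measured genes all rose. Not passing it does not show that a list stayed unchanged.

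**Figure D1:**
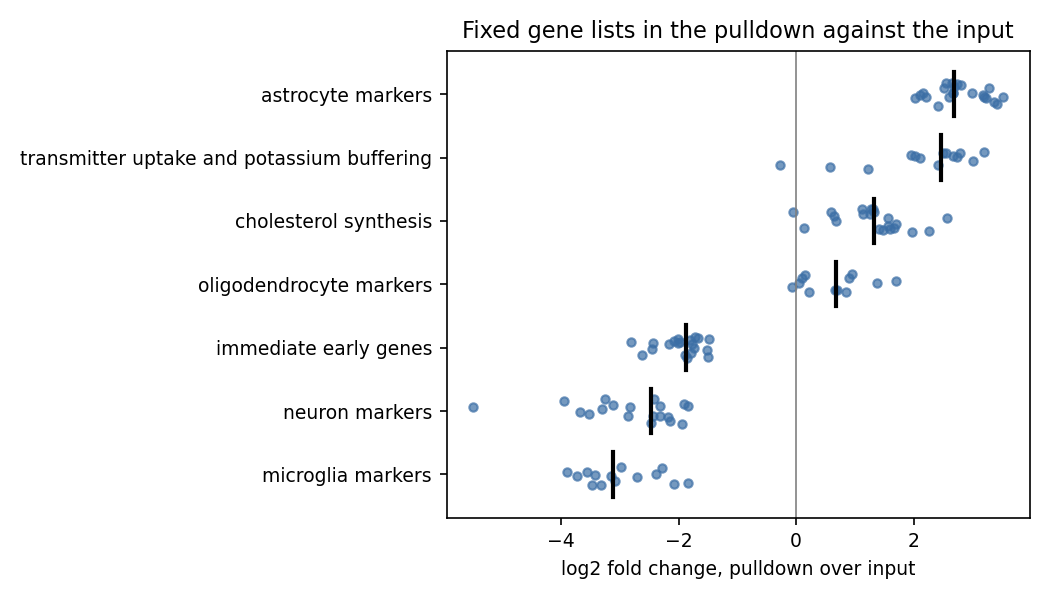
Log2 fold change of each measured gene of 7 gene lists in 16 pulldown libraries over 5 inputs; each point is a gene and each bar the median of its list. The astrocyte markers centre on 2.68 and the neuron and microglia markers on -2.46 and -3.11.

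Dark rearing was compared with normal rearing at the same age, to see how astrocyte transcripts differ when the cortex has developed without vision. Fos, an immediate early transcription factor (chromosome 12, 85473890 to 85477273), fell from 55.9 ± 24.0 FPKM in 3 normally reared libraries to 7.63 ± 1.18 FPKM in 4 dark-reared libraries. The log2 fold change of Fos was -2.64 ± 0.34 with an adjusted p of 0.0152 in limma, and all 4 dark-reared libraries lay below all 3 normally reared ones. The other genes of the list lay the same way. All 20 measured immediate early genes had negative fold changes, with a median of -1.42, and 18 passed when adjusted over the list alone, against 1 over all genes. Dusp1, a phosphatase of MAP kinases, was at -1.64 ± 0.25 (adjusted p = 0.0599), Btg2, an antiproliferative factor, at -1.46 ± 0.29 (adjusted p = 0.386) and Npas4, a transcription factor induced by calcium entry, at -1.67 ± 0.40. Bdnf, the neurotrophin, was at -1.02 and Arc, a regulator of synaptic receptor trafficking, at -2.08. The camera adjusted p of the list was 5.99e-24, and it was adjusted p = 0.217 with an estimated correlation.

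Astrocyte genes proper showed no call. Gfap was at 0.20 ± 0.23, Aldh1l1 at 0.07 ± 0.12, Gja1 at 0.00 ± 0.36, Gjb6 at -0.10 ± 0.17, and the synapse-regulating factors Chrdl1 and Gpc4 at -0.14 ± 0.41 and -0.08 ± 0.20. The astrocyte membrane protein Mlc1 was at 0.38 ± 0.16, Apoe at 0.42 ± 0.17 and the fatty acid binder Fabp7 at 0.35 ± 0.17, none past the threshold. Serpina3n, a protease inhibitor of reactive astrocytes, was at -1.36 ± 0.67. Neuron markers measured in these pulldowns had a median of -0.74, with 16 of 18 lower, and Camk2a at -1.09 ± 0.37 and Nefl at -1.22 ± 0.48 did not pass (camera adjusted p = 0.000152, and adjusted p = 0.584 with an estimated correlation). Of 76 nuclear genes of the respiratory chain, 70 had positive fold changes with a median of 0.22, among them Ndufc1 at 0.49 and Ndufb11 at 0.47 (camera adjusted p = 6.09e-13, and adjusted p = 0.584 with an estimated correlation). Genes among the 10 with the smallest p also included the postsynaptic scaffold Shank1 at -1.13 and the synaptic exchange factor Iqsec3 at -1.04, without passing. In limma 1 of 11562 genes passed, and 640 had an unadjusted p under 0.05, where chance gives 578. The call on Fos was lost in 6 of the 7 fits that left out 1 library, with adjusted p of 0.173 and 0.169 without normally reared replicates 2 and 3 and of 0.0855, 0.0916, 0.0653 and 0.0527 without dark-reared replicates 1, 4, 5 and 6. Without normally reared replicate 1 the adjusted p was 0.00933 and 3 genes passed, and over the 7 fits the fold change of Fos ran from -2.97 to -2.33. With the neuron markers as a covariate, Fos was at -2.36 ± 0.37 with an adjusted p of 0.210.

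**Figure D2:**
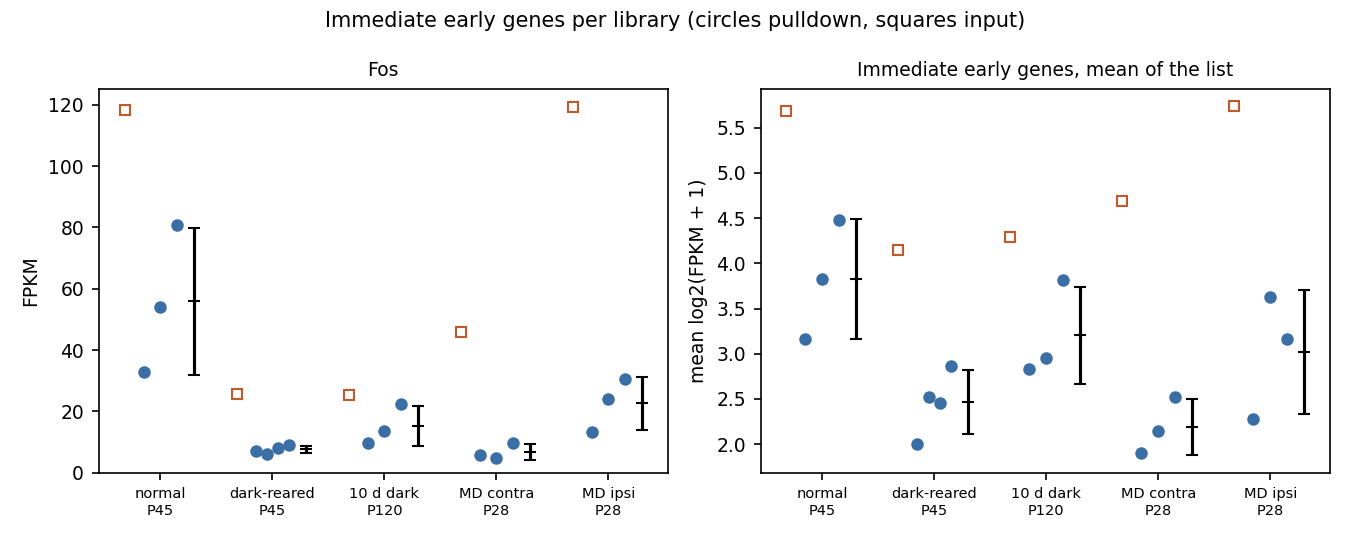
Fos in FPKM and the mean log2(FPKM + 1) of the immediate early genes in each library of the 5 groups; circles are pulldown libraries, squares the single input of each group, and bars the mean ± SD of the pulldowns. The dark-reared pulldowns average 7.63 FPKM of Fos and the normally reared ones 55.9 FPKM.

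Monocular deprivation was read by setting the cortex contralateral to the closed eye against the ipsilateral cortex, both at day 28. All measured immediate early genes had lower values on the contralateral side, though no single gene passed over all genes and the list did not pass with an estimated correlation. Fos averaged 6.83 ± 2.53 FPKM contralaterally and 22.6 ± 8.76 FPKM ipsilaterally (n = 3 each), a log2 fold change of -1.56 ± 0.36. Dusp1 was at -1.01 ± 0.27 and Npas4 at -1.35 ± 0.43. All 20 immediate early genes had negative fold changes, with a median of -0.80, and 3 of them, Fos, Dusp1 and Npas4, passed when adjusted over the list alone, against 0 over all genes (camera adjusted p = 1.10e-21, and adjusted p = 0.214 with an estimated correlation). The log2 ratio of pulldown to single input for Fos was -2.585 contralaterally and -2.35 ipsilaterally, near the neuron marker medians of -2.52 and -2.61. Between these 2 inputs the immediate early genes had a median log2 difference of -1.05. A change in astrocytes thus cannot be told apart from a change in neurons whose RNA was carried over.

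For cholesterol synthesis no gene passed. All 21 genes of the list had negative fold changes, with a median of -0.27, Fdps, which makes farnesyl diphosphate, at -0.44 ± 0.20 and Nsdhl, a sterol dehydrogenase, at -0.29 ± 0.14, and 0 passed when adjusted over the list alone (camera adjusted p = 1.57e-07, and adjusted p = 0.265 with an estimated correlation). Among antigen presentation and interferon genes 9 of 10 had positive fold changes, with a median of 0.30, Ifit3 at 0.85 ± 0.40 and the class I gene H2-D1 at 0.28 ± 0.14, and 0 passed when adjusted over the list alone (camera adjusted p = 4.19e-10, and adjusted p = 0.166 with an estimated correlation). Contralateral replicate 3 alone carried this difference, with a list mean on the log2 scale of 3.79 against 2.48 and 2.42 in contralateral replicates 1 and 2 and 2.63, 2.40 and 2.47 in the ipsilateral libraries. Igfbp2, a binder of insulin-like growth factors, averaged 174.2 ± 43.7 FPKM contralaterally and 308.7 ± 15.4 FPKM ipsilaterally, a log2 fold change of -0.85 ± 0.19. Fabp7 was at -0.53 ± 0.18, the transcription factor Etv4 at -0.63 ± 0.21 and the trophic factor Cntf at 0.56 ± 0.20. Gfap was at 0.03 ± 0.25, Gja1 at 0.06 ± 0.38, Aldh1l1 at -0.14 ± 0.13, Chrdl1 at -0.11 ± 0.44 and Gpc4 at -0.11 ± 0.21. In limma 0 of 11562 genes passed and 84 had an unadjusted p under 0.05, fewer than the 578 expected by chance. That fit ignored the likeness of same-numbered libraries described below, which enlarges the error of this difference. The low count thus does not show that genes stayed unchanged. Without contralateral replicate 3, 1 gene passed, the microRNA gene Mir7082, at -2.38 with an adjusted p of 0.0102, against -1.82 with all libraries.

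Libraries of the contralateral and ipsilateral side with the same number deviated alike from their group means across genes, with correlations of 0.802, 0.790 and 0.903, and genes are not independent replicates. A paired fit with the replicate number as a block gave 1 gene, with 705 at an unadjusted p under 0.05. In that fit 8 of 18 immediate early genes and 16 of 21 cholesterol synthesis genes were lower when adjusted over the list alone. Their list tests in the blocked fit were adjusted p = 4.64e-17 and adjusted p = 1.81e-15 with the preset correlation and adjusted p = 0.741 for each with an estimated correlation.

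Whether dark rearing and monocular deprivation acted on the same genes was tested from 4 groups that share no library. The difference of the effects passed for 0 of 11562 genes in limma, with 116 at an unadjusted p under 0.05, in a fit that ignored the numbered pairs. With the numbers of the contralateral and ipsilateral libraries as a block, an alternative added after seeing the data, 738 had an unadjusted p under 0.05 and 1 gene passed, Etnppl, a phospholyase of astrocytes named after its value was seen, at -0.95 ± 0.13 (adjusted p = 0.0447). Across genes the fold changes correlated with a Pearson r of 0.0428 and a Spearman rho of 0.0251, and with 0.159 and 0.164 over the 6347 genes with pulldown levels at or above 0.75 of input. Of the 100 genes with the smallest p among those lower in dark rearing, 94 were also lower contralaterally, with a median of -0.21 (camera p = 5.91e-14, and p = 0.189 with an estimated correlation). The contralateral contrast leaned lower in general, with a median of -0.06 over all genes. In it 65 of 76 respiratory chain genes, 18 of 22 astrocyte markers and 7 of 18 neuron markers were lower, so the 94 do not all stand for a shared effect. Of the corresponding 100 genes higher in dark rearing 49 were lower contralaterally, with a median of 0.00 (camera p = 0.00511, and p = 0.453 with an estimated correlation), and over all genes 56.8% had the same sign. The correlation over all genes turned with single libraries, from -0.373 without contralateral replicate 1 and -0.246 without ipsilateral replicate 2 to 0.273 without contralateral replicate 3 and 0.494 without ipsilateral replicate 1. Without contralateral replicate 3 the difference of the effects passed for 1 gene.

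Mice kept in the dark for 10 days until day 120 were compared with normally reared mice at day 45, so that age and darkness changed together. Microglial transcripts were higher, Gpx8 was lower, and cholesterol synthesis genes were lower as a group in the older dark-exposed pulldowns. Astrocyte markers lay lower beside them, 20 of 22 with a median of -0.27 and 0 passing when adjusted over the list alone (camera adjusted p = 4.71e-05, and adjusted p = 0.509 with an estimated correlation). The blood markers Hbb-bs and Hbb-b1, at 1.34 and 1.35, both passed when adjusted over the list alone and neither over all genes (camera adjusted p = 0.000725, and adjusted p = 0.206 with an estimated correlation), and the 3 measured endothelial markers had a median of 0.75 with 0 passing. The 2 blood markers had an estimated correlation of 0.99999, so they hardly count as separate measurements. Over all 8 listed blood genes the log2 mean was 1.37, 0.14 and 0.73 in dark-exposed replicates 1, 3 and 4. In normal rearing it was 0.09 to 0.22, so replicate 3 did not share the rise. Ctss (chromosome 3, 95526786 to 95556403) rose from 1.93 ± 0.51 FPKM to 14.4 ± 3.66 FPKM (n = 3 each), a log2 fold change of 2.38 ± 0.23 with an adjusted p of 0.000441 in limma. The other increases were the complement genes C1qc at 2.40 and C1qa at 2.30, the receptor Csf1r at 1.87, the selectin ligand Selplg at 1.71, Laptm5 at 1.54, Tmem119 at 1.52, Cx3cr1 at 1.48 and Fcrls at 1.37. In the microglia list 7 of 12 measured genes rose over all genes and 12 when adjusted over the list alone, with a median of 1.501 (camera adjusted p = 2.43e-50, and adjusted p = 0.000815 with an estimated correlation).

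Gpx8, a peroxidase of the endoplasmic reticulum (chromosome 13, 113042753 to 113046410), had 21.8 ± 2.15 FPKM in normally reared and 10.3 ± 1.61 FPKM in dark-exposed pulldowns, and fell by 1.02 ± 0.15 on the log2 scale (adjusted p = 0.0125). All 21 cholesterol synthesis genes had negative fold changes, with a median of -0.50, and 4 passed when adjusted over the list alone, against 0 over all genes (camera adjusted p = 3.49e-21, and adjusted p = 0.0158 with an estimated correlation). With the mean of 6 lists of other cell types as a covariate the median was -0.58 and the list had an adjusted p = 0.169 with an estimated correlation. With the replicate number as a block the median was -0.51, 0 genes passed when adjusted over the list alone, and the list had an adjusted p = 0.751 by camera with an estimated correlation. That blocked fit rests on 2 pairs, the libraries numbered 1 and 3. Within the list Dhcr7, the last enzyme on the route to cholesterol, was at -0.67 ± 0.15 and Msmo1 at -0.77 ± 0.21. Fabp7 was at -0.97 ± 0.18 (adjusted p = 0.0668), Lcat, which esterifies cholesterol, at -0.63 ± 0.15, Igfbp2 at -0.84 ± 0.19 and Bmp6 at 0.98 ± 0.20, without passing. Fos was at -1.79 ± 0.36 (adjusted p = 0.124), and 19 of 20 immediate early genes had negative fold changes with a median of -0.62, 2 of them passing when adjusted over the list alone (camera adjusted p = 2.06e-11, and adjusted p = 0.3197 with an estimated correlation). Serpina3n was at -2.19 ± 0.72, Gfap at -0.26 ± 0.25, Aldh1l1 at -0.19 ± 0.13, Gja1 at -0.43 ± 0.38, Gjb6 at -0.32 ± 0.18, Chrdl1 at -0.46 ± 0.44 and Gpc4 at -0.35 ± 0.21.

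In total 10 of 11562 genes passed, 9 higher and 1 lower, and 442 had an unadjusted p under 0.05 in limma, where chance gives 578. Ctss, Csf1r, Laptm5 and Cx3cr1 kept their calls in all 6 fits that left out 1 library, while Gpx8, C1qc and Fcrls kept theirs in 2 of 6 and C1qa in 3 of 6. C1qc, Fcrls and C1qa lost their calls without normally reared replicate 1 (adjusted p = 0.104 each), normally reared replicate 3 (0.0977, 0.0977 and 0.0902) and dark-exposed replicate 1 (0.118 each), and C1qc and Fcrls also without dark-exposed replicate 4 (0.0543 and 0.0718). For Gpx8 the adjusted p was 0.0502 and 0.0643 without normally reared replicates 2 and 3 and 0.118 and 0.0789 without dark-exposed replicates 1 and 4. Tmem119 passed the filter at a mean of 1 FPKM in 4 of these fits and Selplg in 5, and both kept their calls there. The count was 4 without dark-exposed replicate 1, where 8 of the 10 genes were tested. It was 6 without dark-exposed replicate 4 or normally reared replicate 3. The count was 0 when only genes with a mean above 5 FPKM were tested, a filter that kept 2 of the 10. It was 0 with the replicate number as a block, and 1, not among the 10, with the mean of 6 lists of other cell types as a covariate. The microglia markers kept their size in the last 2 of these fits, but neither fit can decide how firm their rise is. The covariate includes these markers, and with it the median of the oligodendrocyte markers went from 0.07 to -0.97. The block rests on 2 pairs, the libraries numbered 1 and 3. The median of the microglia markers was 1.51 with the covariate, where 11 of 12 passed when adjusted over the list alone (adjusted p = 0.0085 with an estimated correlation), and 1.70 with the block, where 13 of 13 did (adjusted p = 0.751 with an estimated correlation).

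**Figure D3:**
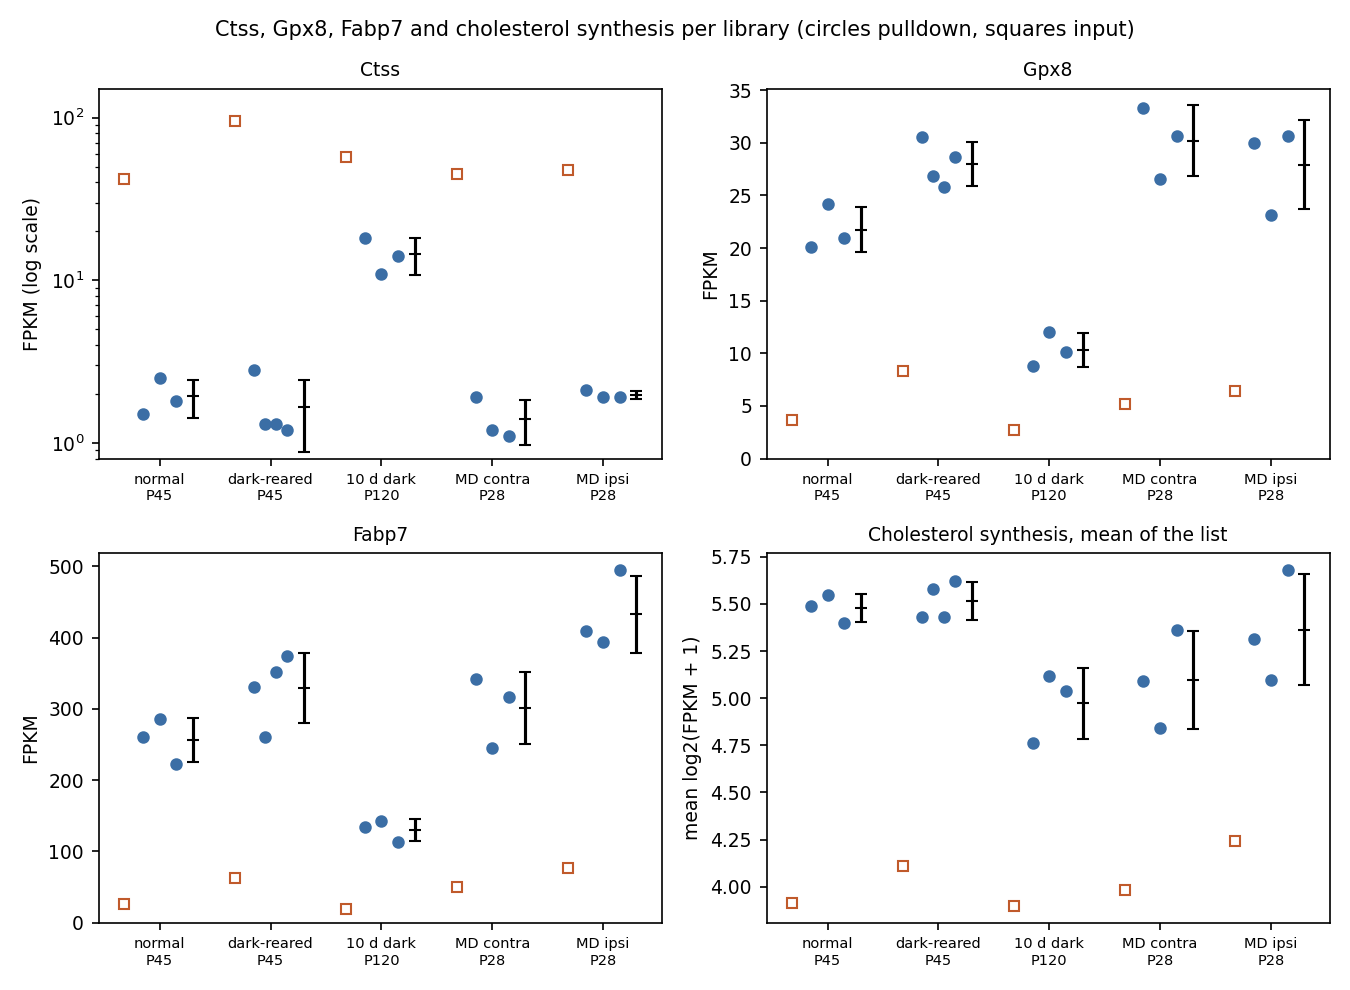
Ctss (log axis), Gpx8 and Fabp7 in FPKM and the mean log2(FPKM + 1) of the cholesterol synthesis genes in each library of the 5 groups; circles are pulldowns, squares the single input of each group, and bars the mean ± SD of the pulldowns. Ctss averages 14.4 FPKM and Gpx8 10.3 FPKM in the 10-day dark pulldowns.

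The 10-day dark group was also set against the dark-reared group, a contrast in which age and the timing of darkness changed together. Microglial transcripts were higher in the 10-day group, as were the spectrins Sptb and Sptan1, and Gpx8, Fabp7 and a few other transcripts were lower. Of 22 astrocyte markers 21 had negative fold changes, with a median of -0.27 and 0 passing when adjusted over the list alone (camera adjusted p = 8.20e-07, and adjusted p = 0.503 with an estimated correlation). Gpx8 averaged 28.0 ± 2.11 FPKM in 4 dark-reared and 10.3 ± 1.61 FPKM in 3 dark-exposed libraries, a fall of 1.37 ± 0.14 on the log2 scale (adjusted p = 0.000246). Fabp7 (chromosome 10, 57784881 to 57788450) averaged 329.1 ± 49.6 and 130.3 ± 15.6 FPKM, a fold change of -1.32 ± 0.17 (adjusted p = 0.000707). Other decreases were the transcription factor Tead2 at -1.003, the monooxygenase Fmo1 at -0.86, Dhcr7 at -0.81, Igfbp2 at -0.80, the lipid phosphatase Plpp4 at -0.78, Btbd17 at -0.75, Sp6 at -0.67 and Lcat at -0.61.

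All 12 measured microglia markers rose, with a median of 1.71, led by C1qb at 2.56, Ctss at 2.55 and C1qa at 2.42 (camera adjusted p = 2.87e-25, and adjusted p = 0.0156 with an estimated correlation). The 2 measured blood markers had a median of 1.06, and both passed when adjusted over the list alone and neither over all genes (camera adjusted p = 0.102, and adjusted p = 0.542 with an estimated correlation). Over all 8 listed blood genes the log2 mean of dark-exposed replicate 3, 0.14, lay within the dark-reared range of 0.10 to 0.50. All 21 cholesterol synthesis genes had negative fold changes, with a median of -0.53; 1 fell over all genes, Dhcr7, and 8 when adjusted over the list alone (camera adjusted p = 1.99e-18, and adjusted p = 0.0263 with an estimated correlation). In the list of lipid carriers 2 of 10 genes fell, Fabp7 and Lcat, while 4 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.00151, and adjusted p = 0.0415 with an estimated correlation). With the mean of 6 lists of other cell types as a covariate, 1 cholesterol synthesis gene and 1 lipid carrier fell when adjusted over the list alone, with medians of -0.63 and -0.35, and each list had an adjusted p = 0.0729 with an estimated correlation. Spectrins were among the largest increases, with Sptb at 2.32 ± 0.29 and Sptan1 at 2.26 ± 0.37, beside the neuronal long RNAs Meg3 at 2.28 and Snhg11 at 2.27 and the actin binder Ppp1r9a at 2.09. All 18 neuron markers had positive fold changes, with a median of 0.94, and 2 passed over all genes, Camk2a at 1.65 and Gad1 at 0.99, and 4 when adjusted over the list alone (camera adjusted p = 4.84e-06, and adjusted p = 0.503 with an estimated correlation). The 20 immediate early genes had a median of 0.75, all positive and 0 passing when adjusted over the list alone, with Arc at 1.65 ± 0.51 (camera adjusted p = 0.000511, and adjusted p = 0.613 with an estimated correlation). With the covariate for other cell types their median was 0.23 (camera adjusted p = 0.891, and adjusted p = 0.986 with an estimated correlation). Gfap was at -0.46 ± 0.23, Aldh1l1 at -0.26 ± 0.12, Gja1 at -0.42 ± 0.36, Gjb6 at -0.22 ± 0.17, Chrdl1 at -0.32 ± 0.41 and Gpc4 at -0.26 ± 0.20.

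Of 11562 genes 287 passed, 276 higher and 11 lower, and 254 of the 276 had pulldown levels below 0.75 of input. The count fell to 10 among genes at or above 0.75 of input, to 55 with the neuron markers as a covariate and to 0 with the mean of 6 lists of other cell types as a covariate. Those 6 lists include the neuron and microglia markers, so that fit adjusts such genes for their own level. The count was 3463 with the replicate number as a block, where the numbers are not known to pair animals. That fit held only these 2 groups, which share the numbers 1 and 4, so its group difference rests on 2 pairs. With that block the microglia, cholesterol synthesis and lipid carrier lists each had an adjusted p = 0.537 by camera with an estimated correlation. Adjusted over the list alone, 12 of 12 microglia markers were higher there and 20 of 21 cholesterol synthesis genes lower. Leaving out 1 library gave 119, 151, 102 and 212 genes without dark-reared replicates 1, 4, 5 and 6 and 101, 150 and 69 without dark-exposed replicates 1, 3 and 4. Gpx8, Fabp7, Sptb, Sptan1, Ppp1r9a, C1qb, Ctss and C1qa kept their calls in all 7 of these fits, Dhcr7 in 6, Plpp4 in 5 and Meg3 in 4. Tead2, Fmo1 and Igfbp2 kept theirs in 2, Camk2a, Gad1 and Snhg11 in 1, and Btbd17, Sp6 and Lcat in 0. Without dark-exposed replicate 4 the adjusted p was 0.0569 for Plpp4, 0.122 for Meg3, 0.108 for Tead2, 0.109 for Fmo1, 0.148 for Igfbp2, 0.212 for Camk2a, 0.178 for Gad1, 0.147 for Snhg11, 0.218 for Btbd17, 0.181 for Sp6 and 0.226 for Lcat, and without dark-exposed replicate 1 it was 0.0548 for Dhcr7.

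The ipsilateral cortex at day 28 was compared with normal rearing at day 45, a contrast that mixes age with deprivation. The pattern was one of values without calls. Slc1a2, the main glutamate carrier of astrocytes, averaged 1190 FPKM ipsilaterally and 2157 FPKM in normally reared pulldowns, with a log2 fold change of -1.10, and Gja1 was at -0.80. The list of transmitter uptake and potassium buffering had log2 means of 6.94, 6.48 and 7.69 in ipsilateral replicates 1, 2 and 3, against 7.43 to 7.62 in normal rearing. Its lower values thus sat in replicates 1 and 2. Sparc, a secreted regulator of synapse formation, was at 0.93, Fabp7 at 0.75, Mbp, a myelin protein, at 0.91 and the respiratory genes Ndufs5 and Ndufa3 at 1.21 and 1.08. Fos was at -1.25 and Btg2 at -1.03, and all 20 immediate early genes had negative fold changes, with a median of -0.83 and 3 passing when adjusted over the list alone (camera adjusted p = 7.70e-05, and adjusted p = 0.558 with an estimated correlation). Neuron markers had a median of -0.44, with 13 of 18 lower, and astrocyte markers of -0.30, with 16 of 22 lower. Oligodendrocyte markers had a median of 0.47, with 9 of 12 higher (camera adjusted p = 7.86e-06, and adjusted p = 0.558 with an estimated correlation). Of 76 respiratory chain genes 71 had positive fold changes, with a median of 0.42 and 0 passing when adjusted over the list alone (camera adjusted p = 1.13e-26, and adjusted p = 0.558 with an estimated correlation). Of 17 clock genes 16 had negative fold changes, with Bhlhe40 at -0.61 and Hlf at -0.72 and 0 passing when adjusted over the list alone (camera adjusted p = 0.000945, and adjusted p = 0.558 with an estimated correlation). Gfap was at -0.23, Aldh1l1 at -0.08, Gjb6 at -0.49, Chrdl1 at -0.54 and Gpc4 at -0.63. In limma 0 of 11562 genes passed, with a smallest adjusted p of 0.114, and 1108 had an unadjusted p under 0.05. All of these values stand on a median over all genes of -0.16, which was 0.00 after quantile normalization, and the count became 585 without the 3 pulldown libraries, numbered 3, that held little ribosomal RNA.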

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

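The tests of explanations below were chosen only after the results were seen; the search for single libraries far from the others and the counts over other splits of the libraries were set beforehand.

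In the dark-reared group, the only one with 4 pulldown libraries, each value was searched for 1 library lying apart from the rest, by the gap to its neighbour as a share of the range. Chance picks out about 1 in 20 groups; here 2 of 33 lists and measures and 10 of 125 genes were picked out, with 5% given by chance. Replicate 1 had the highest mean of the microglia markers (share 0.9678; 1.48 against 1.05 to 1.06) and the lowest mean of the activin, BMP and TGF-beta genes (share 0.8301; 3.35 against 3.44 to 3.46). Replicate 1 was also highest for Ctss (0.9375; 2.8 FPKM against 1.2 to 1.3), C1qa (0.850; 3.5 against 1.5 to 1.8) and C1qc (0.9655; 4.2 against 1.3 to 1.4), and lowest for Elmo1 (0.8824; 2.6 against 4.1 to 4.3) and Bmp6 (0.8333; 1.4 against 1.9 to 2.0). Replicate 4 was highest for Gja1 (0.9317; 676.4 against 538.7 to 548.1) and Chrdl1 (0.907; 28.2 against 19.6 to 20.4). Replicate 5 was highest for Serpina3n (0.9761; 61.8 against 7.3 to 8.6). Replicate 6 was lowest for Gpc4 (0.8333; 10.2 against 11.2 to 11.4) and Pdgfrb (0.9091; 13.8 against 17.8 to 18.2).

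Microglia markers were higher in the 10-day dark pulldowns than in the normally reared ones, and the lists of other cell types argue against a lower share of astrocyte RNA as the whole cause, though 20 of 22 astrocyte markers were lower with a median of -0.27. Among those with at least 6 measured genes the highest upper quartile was 0.62 (mural and meningeal markers; 0.32 for 18 neuron markers), and the lower quartile of the microglia markers was 1.24. With fewer genes, 3 endothelial markers had a median of 0.75 and 2 blood markers of 1.35. Microglial RNA carried into the pulldowns stays open: 11 of 12 markers gained a share of their input level within 2-fold of the median of 23.2% (range 9.66% to 27.9%), and all 12 had been required. More microglial RNA in the tissue stays open too, with a median difference of 0.25 and 11 of 12 markers higher between single inputs, while 14 of 14 were lower in the 10-day dark than in the dark-reared input (median -0.61), where the pulldown median was 1.71. Age and darkness changed together here, so either may be the cause, and neither was tested.

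Fos was lower after dark rearing, at -2.64 ± 0.34 with an adjusted p of 0.0152. With the neuron markers as a covariate it was -2.36 ± 0.37 with an adjusted p of 0.210; the call ended with a smaller fold and a larger error, and most of the fold stood, which argues against a smaller neuronal share as the whole cause. With ribosomal RNA as a covariate it was -2.38 ± 0.25 with an adjusted p of 0.00165, but without the 3 libraries low in ribosomal RNA it was -2.33 ± 0.31 with an adjusted p of 0.0684, and the call was lost. Most of the fold stood in both fits, which argues against that library difference as the whole cause. Lower Fos in neurons whose RNA was carried over stays open. The log2 ratio of pulldown to input for Fos was -1.07 in the normally reared group, above all 20 neuron markers (highest -1.38). It was -1.63 in the dark-reared group with 1 marker above it, each from a single input. The neuron markers had median ratios of -2.09 and -2.98 in these groups, and the 20 immediate early genes of -1.76 and -1.63. In the contralateral and ipsilateral groups 11 and 6 neuron markers lay at or above Fos, and 0 in the 10-day dark group. Fos was also lower in the single dark-reared input than in the normally reared one. Absence of vision stays open as well and cannot be told apart from the carried-over RNA.

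Genes higher in the 10-day dark group than in the dark-reared group may in part reflect a larger neuronal share of the pulldowns. The neuron markers had a median of 0.94 (quartiles 0.65 to 1.21) beside 1.10 for the 276 genes (0.90 to 1.42), and 92.0% of these genes, against 45.1% of those tested, lay below 0.75 of input. With the neuron markers as a covariate 49 of the 276 were called, and all 276 stayed more than 2 errors above 0. Their median went from 1.10 to 0.81, with a median error of 0.22 before and 0.21 after. These genes were chosen for their high values in the same libraries, so that fit cannot decide whether this share is the whole cause. With the covariate for other cell types, 0 of the 287 genes called in either direction passed. That covariate includes the neuron and microglia markers, so it adjusts such genes for their own level. For transcript length and GC content, 625 pulldown-enriched genes matched in both had a median of -0.0721 (quartiles -0.23 to 0.06). Another 390 matched genes below 0.5 of input had a median of 0.53 (0.32 to 0.81). Both sets left out the called genes. Genes alike in length and GC thus moved differently with their level over input, so these traits alone do not account for the rise. A part for them among genes below input was not tested. What raised these genes stays open, and age and the timing of darkness were not separated.

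Other splits of the same libraries were counted for each comparison. For dark against normal rearing 1 of 35 splits, the real one, gave as many genes (1, highest other 0). That count rests on Fos alone, whose call was lost in 6 of 7 fits that left out 1 library, and 6 comparisons were made, so chance is not ruled out for it. For the 10-day dark against the dark-reared group it was also 1 of 35 (287, highest other 0), the smallest share that 35 splits can give. With 6 comparisons made, these splits alone do not rule out chance for that count either. For pulldown against input 1 of 100 splits did (9300, highest other 6869, a split that exchanged 1 input for a pulldown). The 10 splits of 3 against 3 are too few for a share under 0.05. For the 10-day dark against normal rearing, 1 of 10 gave as many (10, highest other 0), and for the ipsilateral cortex against normal rearing 10 of 10 (0, highest other 0, with 1108 genes at an unadjusted p under 0.05 in limma). For the contralateral against the ipsilateral cortex 10 of 10 did (0 in limma, with 84 at an unadjusted p under 0.05, highest other 2819). The splits with 2819 and 1994 genes point to a structure of the samples; both kept the 2 libraries numbered 3 together, as did 2 splits that gave 0. The 3 other splits that part all 3 pairs gave 0.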

How the results depend on the processing

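The covariates for neuron markers and ribosomal RNA, scaling without ribosomal RNA, fits without monocular pair 2 or without the 3 pulldowns low in ribosomal RNA, list tests with the block, every alternative for the difference of effects and the fits leaving out 1 library for the correlation of effects were chosen only after the results were seen; the other tests were set beforehand.

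Counts of genes that moved by more than 1.5-fold are given here, and for each the cause was not tested unless fewer genes or libraries explain it. Pulldown against input (9300) gave 6070 among genes above 5 FPKM, with fewer genes tested. Dark against normal rearing (1) gave 2 with pseudocount 5, the filter at 5, quantile normalization, median-ratio scaling, the covariate for other cell types, scaling without ribosomal RNA and without pair 2; 27 with array weights; 0 among genes at or above 0.75 of input, 0 with the neuron covariate and 0 without the 3 low libraries. Contralateral against ipsilateral (0; 84 at an unadjusted p under 0.05 in limma) gave 1 with the replicate block and 1 without the low libraries. The 10-day dark against normal rearing (10) gave 20 with pseudocount 5, 73 without a filter, 258 with array weights and 27 with the ribosomal RNA covariate. It gave 0 with the filter at 5, which kept 2 of the 10, 0 with the block and 16 without pair 2. It gave 1 each for genes at or above 0.75 of input, only the groups compared and the covariate for other cell types. The 10-day dark against dark rearing (287) gave 493 without a filter, 151 with the filter at 5, 4147 with array weights, 10 at or above 0.75 of input, 1748 with only the groups compared, 0 with the covariate for other cell types, 55 with the neuron covariate, 635 with the ribosomal RNA covariate, 3463 with the block, 669 without pair 2 and 578 without the low libraries. Ipsilateral against normal rearing (0; 1108 unadjusted) gave 1 with array weights, 85 with the ribosomal RNA covariate and 585 without the low libraries. The difference of the effects (0; 116 unadjusted) gave 1 without the low libraries and 1 with the monocular pairs as a block (738 unadjusted), and the correlation of effects (0.0428) was -0.276 without pair 2.

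Lists called with the preset correlation numbered 19 for pulldown against input, 14 for dark rearing, 5 for contralateral against ipsilateral, 17 and 15 for the 10-day dark group against normal and dark rearing, and 10 for ipsilateral against normal rearing. With an estimated correlation they were 0, 0, 0, 2, 3 and 0, and with fry 28, 0, 0, 2, 3 and 0. The neuron covariate gave 6 for dark rearing, 4 for the 10-day dark against dark rearing and 16 for ipsilateral against normal rearing, and the block gave 11 for contralateral against ipsilateral.

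Leaving out 1 library gave 8752 to 9476 genes for pulldown against input, 0 to 3 for dark rearing, 0 to 1 for contralateral against ipsilateral, 4 to 11 and 69 to 212 for the 10-day dark group against normal and dark rearing, 0 to 0 for ipsilateral against normal rearing, 0 to 1 for the difference and -0.373 to 0.494 for the correlation. Of the named genes 1 reversed: Prox1 in pulldown against input, -0.32, was 0.00536 with an adjusted p of 0.969 under quantile normalization. The replicate block was not run for dark against normal rearing, and 1 fit with array weights stopped before full convergence. For the 10-day dark group the block rested on 2 pairs of shared numbers in each comparison. Rounding to 0.1 FPKM limits genes near 1 FPKM, and counting error could not be separated from it.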

Other observations

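The list values of the single inputs were looked at only after the pulldown results were seen, as was their place among 10000 random lists matched in mean level.

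Each group had 1 input, so differences between inputs are values without replicates, and the percentiles among random lists are not p values. Immediate early genes had a median log2 difference of -1.36 between the dark-reared and the normally reared input, of -1.05 between the contralateral and the ipsilateral input and of -1.45 between the 10-day dark and the normally reared input, with 20 of 20 genes lower and percentile 0 each time. Between the ipsilateral and the normally reared input the median was 0.14, with 12 of 20 higher (percentile 16.1), and between the 10-day dark and the dark-reared input 0.03, with 11 of 20 higher (percentile 89.1). Fos was 118.3 FPKM in the normally reared input, 25.7 in the dark-reared, 25.3 in the 10-day dark, 46.0 in the contralateral and 119.4 in the ipsilateral input. Antigen presentation and interferon genes had a median of 0.95 between the contralateral and the ipsilateral input, with 9 of 10 higher (percentile 100), and cholesterol synthesis genes of -0.28, with 19 of 21 lower (percentile 0). Between the 10-day dark and the normally reared input the cholesterol synthesis genes had a median of -0.05 (percentile 1.72). Blood markers had a median of 2.33 between the same inputs, with 6 of 6 higher. Microglia markers had a median of 1.00 between the dark-reared and the normally reared input, with 14 of 14 higher (percentile 100), and ribosomal protein genes of 1.39, with 61 of 61 higher (percentile 100). Fabp7 was 19.3 FPKM in the 10-day dark, 62.2 in the dark-reared and 27 in the normally reared input.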
